A study of Mus musculus with 20 samples.

How the data were processed

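Poly(A) RNA of 20 frozen hearts was sequenced as 50 bp paired-end reads on an Illumina HiSeq 2000, per the labels and the series' design text. The design text says that reads were mapped to unique sites of the MGSCv37 C57BL/6J genome with at most 2 mismatches, a paired distance of 130 to 300 and at least 5 reads per mapping. The aligner and the counter are not given in the sources used here, and edgeR is named in the submitters' processing notes without a role or version. The sex of the animals and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

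The authors deposited a table of raw read counts per gene symbol, with 34291 rows and 20 columns (the design text speaks of 34293 genes), and a table of 700 genes whose values are CPM. The CPM deposited by the authors equal the counts of the larger table divided by that table's column total, with no scaling factor, within 0.001 CPM. In it 4 gene names had been turned into spreadsheet date numbers and were matched by their values. The table of counts holds 25 symbols that read as dates and 26 symbols split over 52 rows by locus, which were kept as separate rows. Columns were assigned to a sample by name. That of rapamycin 4 lacks 1 letter of the sample title and was assigned as the only rapamycin title with that number. Groups and library numbers come from the sample titles, in which each number from 1 to 20 occurs in 1 group, so the labels give no pairing. Neither a batch nor a date is given in the labels. The design text gives 10 mice per group, so the replicates are animals, and no 2 libraries of a group agreed within sampling noise (smallest chi-square per degree of freedom 5.56 over 90 pairs).

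All tests were run on the raw counts with R 4.3.3 and edgeR 4.0.16. Genes passing the default filter by expression (13940) were normalised by TMM and tested with the quasi-likelihood F-test of rapamycin against control in all 20 libraries without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.202. Fold changes are log2 of rapamycin over control, and standard errors are the fold divided by the square root of F. Normalised CPM use TMM library sizes, and log2 CPM add a prior count of 2. The totals of 7039514 to 12458309 counts per library set the counting error, which is large for genes of a few CPM.

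Before the data were examined, 28 gene lists and 16 lists of cell markers were fixed and then tested with camera (limma 3.58.1) at a preset correlation of 0.01, as separate families. Lists with fewer than 5 tested members were not tested, which left out the lung and liver list, none of whose 12 members passed the filter. Under camera 18 gene lists were called, 10 up and 8 down, and 5 marker lists, 1 up and 4 down. With a correlation estimated for each list none of the 28 gene lists and none of the 15 marker lists was called (smallest adjusted p = 0.352 and 0.188 with an estimated correlation), while 3 gene lists and 1 marker list had an unadjusted p under 0.05. fry called 6 gene lists and 1 marker list. The gene lists were fatty acid oxidation, endoplasmic reticulum stress and circadian clock (fry adjusted p = 0.0186 each), ATF4 response (0.0219), proliferation (0.0308) and immediate early genes (0.0473). The marker list was macrophages (0.00942). Lists that fry did not call included T and NK cells (0.0533), mesothelium (0.0561), B and plasma cells (0.0778), antigen presentation (0.0903), interferon (0.119) and inflammation (0.175). Older symbols were matched through the synonyms of a RefSeq table for GRCm38.p6, which is another build than the authors', so no coordinates are given.

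The named genes follow a rule that was also fixed before the data were examined: the 12 largest rises and falls among called genes with a mean of at least 2 CPM, up to 4 members with the smallest p of each list that passed or held a called gene, 10 fixed genes, and the 3 smallest p in each direction. Of the fixed genes Il6 and Tnf were not tested because their counts were too low. Of the genes and lists fixed by these rules, some are not reported here. Further genes named beside list counts, Fos, Junb, Sftpc and Scgb1a1 among them, were chosen after their values were seen. Levels of lists in single libraries were compared by 2-sided permutation tests with 100000 resamples.

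The scripts were tested on simulated counts for 13870 genes in groups of 10, of which 200 were changed. Genes changed by log2 0.4, 0.8, 1.2 and 2 were recovered in 50%, 84%, 94% and 98% of cases, and 4.60% of calls were unchanged genes. A simulated list shifted by log2 0.3 was called and none of the other lists was, with the PPAR list left out of that count. The genes were simulated independently of each other, whereas the adult sarcomere list had an estimated correlation of 0.802 in the data. So this run cannot tell how often lists of correlated genes are called falsely. Alternatives included RLE and upper quartile scaling, other filters, thinning, robust estimation, DESeq2 1.42.0, the classic exact test, limma-voom with sample weights, a surrogate variable from sva 3.50.0, the sample number as a covariate and leaving out each library. The alternatives planned for normalised values were not run because the table holds counts. Figures were drawn with matplotlib 3.10.9.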

Results

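RNA was sequenced from 20 whole hearts of C57BL/6 mice, 10 from animals fed 14 ppm rapamycin, an inhibitor of the growth-controlling kinase mTOR, and 10 from age-matched animals on a control diet. Feeding began at 24 months of age and lasted 3 months, so the hearts came from animals of 27 months. The question put by the design is how late-life rapamycin alters the transcriptome of the old heart. The deposited counts summed to 10108314 ± 1109614 reads per library with rapamycin (SD, n = 10, range 8525162 to 12458309) and 9414752 ± 1102463 in controls (SD, n = 10, range 7039514 to 10594335). Each library is named here by its diet and the number in its label.

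In hearts of rapamycin-fed mice 9 of 14 macrophage markers and 2 of 10 T and NK cell markers fell, while 7 of 22 genes of fatty acid oxidation and 4 of 18 immediate early genes rose (edgeR adjusted p under 0.05). The macrophage lysosomal glycoprotein Cd68 fell from 14.6 ± 4.39 to 7.45 ± 1.73 normalised CPM (SD, n = 10 per group). Decr1, an auxiliary enzyme for the oxidation of unsaturated fatty acids, rose from 331 ± 52.0 to 447 ± 42.7 CPM. Egr1, an immediate early transcription factor, rose from 40.2 ± 26.8 to 102 ± 37.0 CPM. Among 13940 genes tested, 469 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 96 rose and 373 fell, and 3024 had an unadjusted p under 0.05. The falls were the larger changes: 138 genes fell and 3 rose by more than 2-fold. These counts include control 19, on which several of the largest falls rested, as given below. Without that library 68.9% of called genes were falls, against 79.5% with it.

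The smallest p-values among genes that rose belonged to Tmem47, a junctional membrane protein (log2 fold change 0.47 ± 0.07, SE, adjusted p = 0.0040 by edgeR), to the clustered protocadherin Pcdhb12 (0.69 ± 0.13) and to 9030418K01Rik (0.50 ± 0.10). Those among genes that fell belonged to Ms4a6c, a membrane protein of myeloid cells (-1.18 ± 0.17), to the heparan sulfate-cleaving enzyme Hpse (-1.25 ± 0.18) and to Gm1966 (-1.14 ± 0.17), each with an adjusted p of 0.0040 by edgeR. In all 10 rapamycin libraries Tmem47 lay above every control library, and Ms4a6c and Hpse lay below every control library. Complete separation of the groups was seen for 10 genes, where chance gives 0.00108% of genes. All 6 of these genes kept their call when any 1 library was left out.

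Among named genes the largest rises were those of Cxcl1, a neutrophil-attracting chemokine (1.43 ± 0.29, adjusted p = 0.0155 by edgeR), Egr1 (1.34 ± 0.30, 0.0200), the immediate early nuclear receptor Nr4a1 (1.22 ± 0.32, 0.0407) and Fbp2, a muscle fructose bisphosphatase (0.77 ± 0.16, 0.0159). They were followed by Cyr61 (0.72), Otud1 (0.65), Art5 (0.65), Dusp1 (0.63), the sodium channel subunit Scn4b (0.61), Ybx2 (0.60), the calcium channel subunit Cacna1s (0.57) and Lonrf1 (0.56). The largest falls were those of the macrophage lectin Chi3l3 (-6.12 ± 1.42, adjusted p = 0.0255 by edgeR), which has near-identical copies that unique mapping may split, the neutrophil alarmins S100a9 (-4.95) and S100a8 (-4.81), and the scavenger receptor Marco (-3.60 ± 0.68, adjusted p = 0.0111). Scnn1a (-3.56), Tspan8 (-3.20), Lcn2 (-3.06), Cbr2 (-2.88), Tnfsf8 (-2.73), the macrophage-secreted Cd5l (-2.70) and Krt7 (-2.52) followed.

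Several of these falls rested on 1 control heart. In CPM without scaling factors, the library of control 19 held 6966 of Sftpc, the surfactant protein of lung alveolar cells, and 18216 of Scgb1a1, a secretory protein of airway epithelium, whereas the medians over the 20 libraries were 0.194 and 0.714. The same library held 1236 normalised CPM of S100a9, against 44.5 in the next highest. Without it S100a9 (-1.54, adjusted p = 0.128 by edgeR), S100a8 (-1.47, 0.160), Scnn1a (-0.84, 0.187), Tspan8 (-0.86, 0.0794), Lcn2 (-1.32, 0.0634), Cbr2 (-0.91, 0.132) and Krt7 (-0.93, 0.0745) no longer passed. Marco (-3.41, 0.00999), Tnfsf8 (-2.81, 0.00990) and Cd5l (-2.68, 0.00796) still did. So did Chi3l3 (-4.35, adjusted p = 0.0403 by edgeR), but it stood at 288 normalised CPM in control 2 and at 0.275 to 10.3 in the 8 other controls, against 0.537 to 3.06 with rapamycin. Without control 19, 472 genes changed, 147 upward and 325 downward, of which 386 were also called with it. Lower amounts of lung transcripts were present in control 1 (363 summed CPM of 5 lung genes), rapamycin 15 (126) and control 20 (64.2), against a median of 1.68. Liver transcripts were present in rapamycin 9, control 7 and rapamycin 4, and thymus transcripts in rapamycin 8 and control 17. A library was counted here if its summed CPM exceeded 10 times the median, with a floor of 0.1 CPM for the median. Libraries under this limit can still hold traces.

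**Figure D1:**
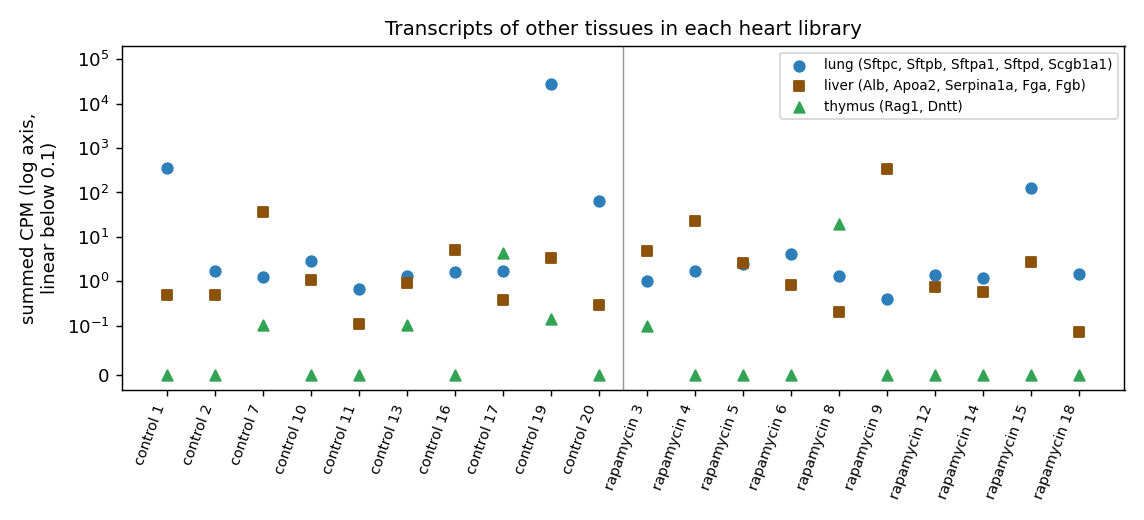
Summed CPM (without scaling factors) of 5 lung, 5 liver and 2 thymus genes in each of the 20 libraries, on a log axis that is linear below 0.1, with controls on the left and rapamycin on the right. Control 19 stands at 28091 CPM for lung genes, and rapamycin 9 at 330 CPM for liver genes.

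Of 14 macrophage markers, 9 fell over all genes tested and 12 when adjusted over the list alone, and the other members also had values below 0. Besides Cd68 (-0.96 ± 0.16, adjusted p = 0.00545 by edgeR) these were led by the folate receptor Folr2 (-0.65 ± 0.14), Emr1, which encodes F4/80 (-0.79 ± 0.18), and the mannose receptor Mrc1 (-0.78 ± 0.17). The list had a median of -0.57 and was lower as a set (camera adjusted p = 5.73e-13). It had an adjusted p = 0.188 with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, gave an adjusted p of 0.00942. Averaged over the list, log2 CPM was 5.20 ± 0.336 in controls and 4.62 ± 0.246 with rapamycin (SD, n = 10 per group, p = 0.000430 by a 2-sided permutation test), and 9 of 10 rapamycin libraries lay below every control. Without control 19 the count of markers that fell was 10 and the median was -0.57.

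Lymphocyte markers had values further below 0, at lower counts. In the T and NK cell list 2 of 10 tested members fell, or 8 when adjusted over the list alone: the adhesion molecule Cd2 (-1.83 ± 0.37, adjusted p = 0.0146 by edgeR) and Nkg7 of cytotoxic granules (-1.92 ± 0.52, 0.0457, and 0.0716 without control 19). The list's median was -1.23 (camera adjusted p = 9.36e-06, adjusted p = 0.344 with an estimated correlation). In the list of B and plasma cells none of 10 tested members passed over all genes, and 9 passed when adjusted over the list alone. Its median was -1.84 (camera adjusted p = 0.000218, adjusted p = 0.344 with an estimated correlation), with the B cell coactivator Pou2af1 at -1.89 ± 0.55 (adjusted p = 0.0589 by edgeR). Thymus transcripts (Rag1 and Dntt) were present in rapamycin 8 and control 17, so they were not in 1 group alone. Whether thymus tissue gave them was not tested.

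The other immune lists and the proliferation list had medians below 0, and few of their members passed over all genes. All 23 tested interferon response genes had values below 0 and Mx1, an antiviral GTPase, fell (-1.05 ± 0.23, adjusted p = 0.0215 by edgeR). All 17 genes of antigen presentation were below 0, and the immunoproteasome subunit Psmb10 fell (-0.41 ± 0.08, 0.0120), with 8 falls when adjusted over the list alone against 1 for interferon. The lists had medians of -0.32 and -0.44 (camera adjusted p = 6.98e-06 and 3.09e-06, with adjusted p = 0.399 and 0.352 with an estimated correlation). In the list of inflammation and NF-kB 4 of 24 tested genes fell and Cxcl1 rose, against 10 falls and 1 rise when adjusted over the list alone. Its median was -0.24 (camera adjusted p = 0.00617, adjusted p = 0.545 with an estimated correlation), and without control 19 the median was -0.14 and 1 gene fell. The camera call was lost without the 4 libraries with lung transcripts (adjusted p = 0.0696). Among 13 tested proliferation genes, all below 0, Mki67 (-1.37 ± 0.32, adjusted p = 0.0271 by edgeR) and the spindle checkpoint kinase Bub1b (-0.80 ± 0.21, 0.0394) fell, 7 fell when adjusted over the list alone, and the median was -0.53 (camera adjusted p = 2.82e-06, adjusted p = 0.352 with an estimated correlation). Bub1b lost its call in 11 of the 20 fits without 1 library, among them that without control 19 (adjusted p = 0.0533 by edgeR), and Mki67 in 4.

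**Figure D2:**
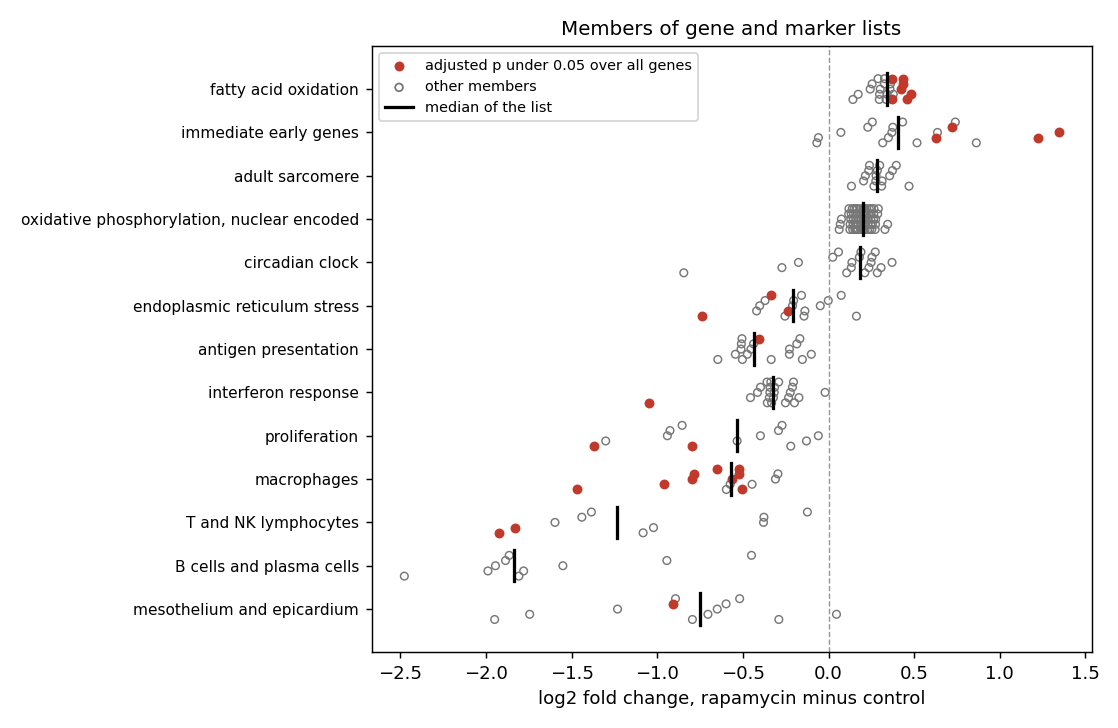
Log2 fold change (rapamycin minus control) of each tested member of 13 lists, with filled red points for genes at an edgeR adjusted p under 0.05 over all genes, open points for the rest and a black bar at the median. All 14 macrophage markers lie below 0 and all 22 fatty acid oxidation genes above 0.

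All 22 members of the fatty acid oxidation list had values above 0. Over all genes 7 rose, and 19 rose when adjusted over the list alone, among them Decr1 (0.43 ± 0.09, adjusted p = 0.0144 by edgeR), Hadh (0.37 ± 0.09, 0.0321), the thiolase Acaa2 (0.43 ± 0.11, 0.0339) and Hadha, a subunit of the trifunctional protein (0.48 ± 0.12, 0.0342). Acaa2 lost its call in 10 of the 20 fits without 1 library, Hadh and Hadha each in 9, and Decr1 in none. The median was 0.34, a fold of 1.27 (camera adjusted p = 2.00e-17, adjusted p = 0.352 with an estimated correlation, fry adjusted p = 0.0186). The mean level of the list was 8.69 ± 0.283 log2 CPM in controls and 9.04 ± 0.170 with rapamycin (SD, n = 10 per group, 2-sided permutation p = 0.00144). Control 19 had the lowest level (7.97), and without it 8 members rose and the median was 0.28. Targets of the lipid-sensing PPAR receptors had a median of 0.17 over 15 genes (camera adjusted p = 0.0114, adjusted p = 0.364 with an estimated correlation): the mitochondrial thioesterase Acot2 rose (0.43 ± 0.11, adjusted p = 0.0385 by edgeR) and the uncoupling protein Ucp2 fell (-0.80 ± 0.19, 0.0282), and 2 rose and 1 fell when adjusted over the list alone.

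**Figure D3:**
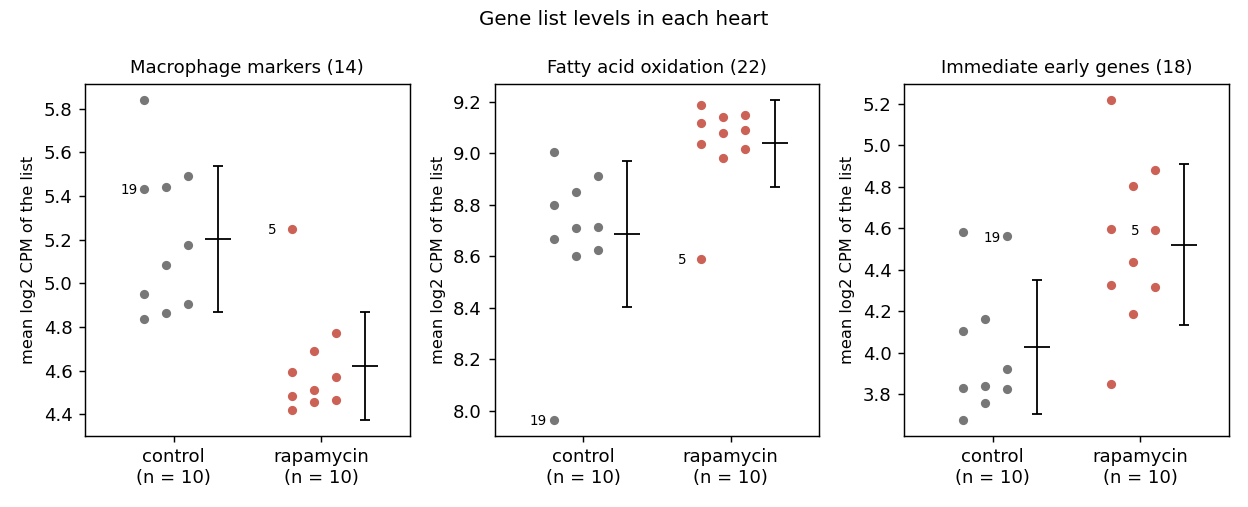
Mean log2 CPM of the members of 3 lists in each heart (points), with the mean and SD of each group of 10 beside them and the points of control 19 and rapamycin 5 numbered. Macrophage levels average 5.20 in controls and 4.62 with rapamycin, fatty acid oxidation levels 8.69 and 9.04, and immediate early levels 4.03 and 4.52.

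No gene of the contractile and respiratory lists passed, whether adjusted over all genes or adjusted over the list alone. The lists had medians above 0 and, with all 20 libraries, passed as sets only at the preset correlation (adjusted p = 0.352 for each with an estimated correlation). Without control 19 fry called the adult sarcomere list (fry adjusted p = 0.0319) but not the others of these lists. The median was 0.28 over 16 adult sarcomere genes, all above 0 (Myl2 0.47 ± 0.16, adjusted p = 0.104 by edgeR), 0.22 over 15 calcium handling genes, 12 of them above 0 (Pln 0.32 ± 0.13, 0.142), 0.20 over 72 nuclear genes of oxidative phosphorylation, all above 0 (Ndufa1 0.26 ± 0.08, 0.0782), and 0.23 over 8 mitochondrially encoded genes, 7 of them above 0 (ND5 0.35 ± 0.12, 0.106). Their camera adjusted p-values were 3.49e-07, 0.00195, 1.01e-16 and 0.00141, and each had an adjusted p = 0.352 with an estimated correlation. Without the 4 libraries with lung transcripts the calcium handling and mitochondrially encoded lists lost their camera call (adjusted p = 0.0592 and 0.0591). Glycolysis genes had a median of 0.12 over 20 members, none called (camera adjusted p = 0.00689, adjusted p = 0.566 with an estimated correlation), and the set lost its call without control 19 (adjusted p = 0.0537). In that library the sarcomere, calcium handling, oxidative phosphorylation and glycolysis lists all had the lowest level of the control group. Without it the median of oxidative phosphorylation was 0.13, and Myl2 (0.38, adjusted p = 0.0430 by edgeR) and Tpm1 (0.27, 0.0307) of the sarcomere list rose.

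Immediate early genes, which respond within minutes to stimulation or handling, had a median of 0.40 over 18 members (camera adjusted p = 2.02e-08, adjusted p = 0.352 with an estimated correlation, fry adjusted p = 0.0473). Over all genes 4 rose, namely Egr1, Nr4a1, the matricellular Cyr61 (adjusted p = 0.0254 by edgeR) and the phosphatase Dusp1 (0.0457), and 9 rose when adjusted over the list alone. Dusp1 lost its call in 14 of the 20 fits without 1 library, Nr4a1 in 11 and Cyr61 in 1. Without control 19, 8 rose, including Fos (2.30-fold, adjusted p = 0.0213 by edgeR) and Junb (log2 0.67 ± 0.16, 0.0208). The mean level was 4.03 ± 0.323 log2 CPM in controls and 4.52 ± 0.388 with rapamycin (SD, n = 10 per group, 2-sided permutation p = 0.00677). In the circadian clock list none of 18 genes passed over all genes, and 2 rose and 1 fell when adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.00332, adjusted p = 0.352 with an estimated correlation), with the activator Arntl at -0.85 ± 0.25 (adjusted p = 0.0589 by edgeR) and Nr1d2, a repressor of the clock, at 0.24 ± 0.08 (0.0812).

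Some genes of the endoplasmic reticulum stress and ATF4 lists fell. In the endoplasmic reticulum stress list 3 of 16 fell, or 9 when adjusted over the list alone: Sdf2l1 (-0.74 ± 0.15, adjusted p = 0.0145 by edgeR), Manf (-0.33 ± 0.09, 0.0405) and the disulfide isomerase Pdia3 (-0.24 ± 0.07, 0.0476), the last of which had an adjusted p of 0.0604 without control 19. Of the 20 fits that each left out 1 library, Pdia3 lost its call in 16 and Manf in 11. The median was -0.21 (camera adjusted p = 3.86e-05, adjusted p = 0.352 with an estimated correlation). In the list of the ATF4 amino acid response 2 of 20 fell on either adjustment, over all genes or adjusted over the list alone: Mthfd2 of the mitochondrial folate cycle (-0.87 ± 0.18, adjusted p = 0.0155 by edgeR) and the serine synthesis enzyme Psat1 (-0.49 ± 0.13, 0.0418, and 0.0564 without control 19). Its median was -0.11 (camera adjusted p = 0.0345, adjusted p = 0.352 with an estimated correlation), and the call was lost without any 1 of rapamycin 5, rapamycin 15, control 1, control 11 or control 17, or without the 4 libraries with lung transcripts (adjusted p = 0.0696).

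Components of the mTOR pathway itself had a median of 0.07 over 26 genes, none called on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.352 with an estimated correlation). Mtor stood at 0.13 ± 0.10 (adjusted p = 0.459 by edgeR), Rptor at 0.10 ± 0.08 (0.497) and Rictor at -0.02 ± 0.08 (0.897), or 0.03 without control 19. Cytosolic ribosomal proteins had a median of -0.06 over 75 genes, none called on either adjustment (camera adjusted p = 0.00245, adjusted p = 0.566 with an estimated correlation). These genes have processed pseudogenes with which they can share reads, so their values are uncertain. Rpl27 stood at 4.31 ± 0.864 CPM in controls (SD, n = 10).

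Markers of cardiac hypertrophy and fibrosis gave no called gene. The hypertrophy and fetal list had a median of -0.17 over 13 genes (camera adjusted p = 0.384, or 0.00108 at a median of -0.35 with the sarcomere level as a covariate, at the preset correlation), with the natriuretic peptides Nppa at -0.58 ± 0.32 (adjusted p = 0.295 by edgeR) and Nppb at -0.61 ± 0.27 (0.184), and the myosin heavy chains Myh6 at 0.40 ± 0.17 (0.189) and Myh7 at 0.42 ± 0.24 (0.315). The sarcomere covariate is largely set by control 19, which had the lowest sarcomere level of all libraries (9.77). The extracellular matrix list had a median of -0.12 over 31 genes, with Col1a1 at -0.26 ± 0.16 (adjusted p = 0.350 by edgeR). Its call (camera adjusted p = 0.0467, adjusted p = 0.693 with an estimated correlation) was lost in 11 of the 20 fits that each left out 1 library.

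Beyond the immune lists, 2 other cell marker lists passed. Mesothelial and epicardial markers had a median of -0.75 over 12 genes (camera adjusted p = 1.23e-05, adjusted p = 0.344 with an estimated correlation). The median was -0.44 without the 9 libraries with lung, liver or thymus transcripts, and -0.46 with the sarcomere level as covariate, which control 19 largely sets. Mesothelin, Msln, fell (-0.91 ± 0.24, adjusted p = 0.0405 by edgeR, and 0.0548 without control 19), and 10 fell when adjusted over the list alone. Smooth muscle and pericyte markers had a median of 0.16 over 14 genes, none called over all genes and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.541 with an estimated correlation), and this call was lost in 8 of the 20 fits that each left out 1 library. Without control 19 its median was 0.10. Endothelial, fibroblast and atrial markers, with medians of -0.02, -0.08 and -0.40, did not pass (camera adjusted p = 0.596, 0.481 and 0.274). Without control 19 the endothelial median was 0.07, and the atrial list passed (camera adjusted p = 0.0286, adjusted p = 0.540 with an estimated correlation), at a median of -0.50. For endothelial cells the median and the mean (-0.03) lay below 0 while the test pointed up.

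In the authors' deposited table of differentially expressed genes, 700 genes are listed with CPM per library, 521 lower and 179 higher with rapamycin. All 700 had the same sign and an unadjusted p under 0.05 in the edgeR fit made here, and 402 were called, where 23.6 are expected by chance. The 402 comprised 311 that fell and 91 that rose, and 67 genes called here are not in that table. Both come from the same libraries, so the overlap compares processing and is not independent evidence.

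The number of changed genes ranged from 165 without rapamycin 18 to 791 without rapamycin 5, the library with the highest macrophage level of its group (5.25) and the lowest level of fatty acid oxidation (8.59). All 57 named genes called with 20 libraries kept their sign in each fit without 1 library, and 24 of them, including Cxcl1, Egr1, Marco, Cd5l, Decr1, Sdf2l1, Mx1, Psmb10, Cd68, Folr2, Emr1, Mrc1 and Cd2, kept their call in each. The call was lost in 13 of the 20 fits for Psat1 and Krt7, in 12 for Nkg7 and Nqo1, in 11 for Msln, in 10 for Acot2, Scnn1a, Tspan8, Lcn2 and Cbr2, in 9 for S100a8, in 8 for Scn4b, in 7 for S100a9, in 6 for Ybx2 and Cacna1s, in 5 for Fdft1, in 4 for Ucp2 and Cnp, in 2 for Chi3l3, and in 1 for Otud1 and Lonrf1.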

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

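The tests on lung tissue in control 19, on other tissues in 9 libraries and on the share of cardiomyocyte transcripts were chosen after the result was seen. Values are the gap of a library to its nearest neighbour in a group of 10 as a share of the group's range, and chance puts about 1 in 20 groups past the 95% limit of the Dixon test used. Of 380 groups of values examined 66 passed. For the lists, genes and library measures given in this text there were 238 groups, of which 41 passed, 33 of them through control 19.

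Control 19 stood alone on the main axis of variation (PC1, gap 0.660). It had the lowest control level of the sarcomere (0.744), calcium handling (0.773), oxidative phosphorylation (0.672), fatty acid oxidation (0.610) and glycolysis lists (0.569), and the highest of the sterol (0.793), endoplasmic reticulum stress (0.484), inflammation (0.652), endothelial (0.727) and neutrophil and mast cell lists (0.493). Among single genes it was lowest for Scn4b (0.533), Ybx2 (0.610), Cacna1s (0.671), Myl2 (0.638), Tpm1 (0.655), Myh6 (0.679), Myh7 (0.508), Pln (0.641), Ndufa1 (0.598), Hadh (0.586), Acaa2 (0.490), Hadha (0.691), Nqo1 (0.531) and 9030418K01Rik (0.482). It was highest for S100a9 (0.494), S100a8 (0.488), Scnn1a (0.602), Tspan8 (0.754), Lcn2 (0.502), Cbr2 (0.504), Krt7 (0.585) and Manf (0.4663).

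Transcripts outside the main test marked other tissues, in CPM without scaling factors: Scgb1a1 at 18216 CPM and Sftpc at 6966 CPM in control 19, the liver gene Alb at 279 CPM in rapamycin 9 and the thymocyte gene Rag1 at 13.01 CPM in rapamycin 8. Rapamycin 5 lay apart from its group with the lowest fatty acid oxidation level (gap 0.654), the lowest Hadha (0.537) and the highest macrophage level (0.575). Rapamycin 8 had the highest proliferation level (0.512), rapamycin 14 the highest Otud1 (0.502), rapamycin 15 the highest Cbr2 (0.780), rapamycin 6 the lowest level of the neutrophil and mast cell list (0.506) and control 1 the highest level of p53 targets (0.508).

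With rapamycin 9 of 14 macrophage markers and 2 of 10 T and NK cell markers fell, and tissue from outside the heart was weighed as the source. Lung in control 19 alone is argued against, since without that library 10 of the 14 macrophage markers were called as lower, among them all 9 called with it. Of the libraries, 11 did not exceed 10 times the median for lung, liver or thymus genes, so traces of these can remain in them. Among these 11 the mean macrophage level was lower by 0.66 log2 units with rapamycin (difference -0.66, exact permutation p = 0.0152 over 462 splits, 2-sided). With the B cell level as a covariate, a proxy for lymphoid tissue, 9 markers were called. The proxy is weak, since control 11 had the lowest B cell level (0.366 log2 CPM) and the highest T and NK cell level (3.33). So this fit cannot decide whether lymphoid tissue was a source of the macrophage markers. A lower content of macrophages in rapamycin-fed hearts, or less transcript per macrophage, may account for the lower macrophage level and stays a hypothesis, which these data cannot split. For the lymphocyte lists, at low counts, lymphoid tissue taken along with some hearts was not excluded.

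With rapamycin 4 of 18 immediate early genes rose. Order of processing, as far as the sample number gives it, is argued against, since 4 genes were still called with that number as a covariate. Time of day may contribute: an index of evening minus morning clock genes was higher with rapamycin by 0.38 log2 units (2-sided permutation p = 0.0241), and with it as a covariate 0 of the 18 immediate early genes were called by edgeR, where only 1 gene of any kind passed and 1219 had an unadjusted p under 0.05. The fold of Egr1 moved little, from 1.34 ± 0.30 to 1.22 ± 0.35 (SE), and the list's median went from 0.40 to 0.49. For Egr1 the call thus ended with a wider error and a higher bar across genes. Why the calls of the other genes ended was not examined. Time of day cannot be told apart from diet while the index goes with it. Within groups of 10 the index showed no clear relation to the list's level in either of 2 relations (controls r = -0.289, p = 0.407, Spearman coefficient -0.309, p = 0.386, and rapamycin r = 0.0786, p = 0.830, Spearman coefficient 0.0303, p = 0.947, by permutation, with adjusted p of 0.772 or more, and r = -0.0490 and 0.347 without the 2 samples farthest from the median index), and the delay between death and freezing was not tested.

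With rapamycin 7 of 22 fatty acid oxidation genes rose. Transcript length and GC content are argued against: after removal of their trend the median over the 22 genes was 0.35, against 0.34 before. A larger share of cardiomyocyte transcripts may account for the pattern but was not decided: the fatty acid oxidation level minus the sarcomere level differed by 0.0041 log2 units between the groups with all 20 libraries (2-sided permutation p = 0.971), and by 0.0722 without control 19 (p = 0.320), beyond the 0.05 that this explanation allowed. Markers of other cell types, which a larger share would lower alike, had medians on both sides of 0. Endothelial, fibroblast and smooth muscle medians were -0.02, -0.08 and 0.16 (0.07, -0.10 and 0.10 without control 19). Macrophage, T and NK cell, B and plasma cell and mesothelial medians were -0.57, -1.23, -1.84 and -0.75. White and brown adipocyte medians were 0.14 and 0.30. The fatty acid oxidation median was 0.17 with the sarcomere level as a covariate. Control 19 stood at 9.77 for that level, against 11.12 or more in each other library, so it largely sets this covariate. No such fit was made without control 19, so the 0.17 cannot decide the question. Regulation within cardiomyocytes, as a hypothesis, stays open as well.

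Chance assignment of hearts to diets was examined with 100 splits of the 20 libraries into groups of 10, the real one included. Only the real split gave 469 or more changed genes, and the highest other count was 1. Chance is thus unlikely for that count, though 100 splits cannot show a share below 1 in 100. As many as the 18 called gene lists were seen in 4 splits, with 19 as the highest other, which is under the 5 in 100 set as the limit. As many as the 5 called marker lists were seen in 46 splits, with 10 as the highest other, so chance is not excluded for that number. The other splits called a median of 11 gene lists and 4 marker lists, so camera at the preset correlation also called lists between groups that mix the diets.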

How the results depend on the processing

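Of the alternatives, those without several libraries, those with a list level as covariate, and estimated correlations without control 19 were chosen after seeing the data. No paired analysis was made because the labels give no pairing and the groups share no replicate numbers, and the alternatives planned for normalised values were not run. Against 469 changed genes (96 up, 373 down, 79.5% down), DESeq2 called 1033 (332 up, 701 down, 67.9% down), limma-voom with quality weights 1076 (418 and 658, 61.2% down), the exact test 803 (674 down) and a surrogate variable 138 (29 and 109). The surrogate variable largely marked control 19 (0.925, with control 1 next at 0.0834). limma-voom gave control 19 its lowest weight (0.133). Rises numbered 59 both without a filter and with the sample number as covariate. Thresholds of 0.1 and 0.01 gave 1180 (332 and 848) and 12 (1 and 11). Without each library in turn the count ran from 165 to 791, rises from 23 to 197 and falls from 142 to 594. It moved by more than 1.5 times without rapamycin 4 (166), 5 (791), 6 (192), 9 (266), 12 (179), 14 (302), 15 (231) or 18 (165), or control 2 (280), 11 (290) or 17 (743). Without control 19, 68.9% of calls were falls. The cause was not tested.

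Without the 4 libraries with lung transcripts 280 genes changed (192 down). Without the 9 with lung, liver or thymus transcripts edgeR called 0, with 1594 at an unadjusted p under 0.05. Leaving out 9 random libraries, 4 with rapamycin and 5 controls, also gave 0 calls in 26 of 50 draws, with a highest count of 889, so fewer libraries alone can do this. With the sarcomere level as covariate 69 genes changed (11 and 58). Control 19 stood at 9.77 for that level, against 11.12 or more in each other library, so it largely sets that covariate. Of the authors' 700 genes, 402 were called, against 257 without a filter, 113 with a surrogate variable, 660 with DESeq2, 612 with limma-voom, 698 and 10 at thresholds of 0.1 and 0.01, 138 to 564 without each library, 223 and 0 without the 4 and 9 libraries, and 230 and 47 with the B cell and sarcomere levels as covariates. The cause was not tested.

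The 18 gene lists called by camera became 0 with estimated correlations, with or without control 19, and 6 with fry. The 5 marker lists became 0, 0 and 1. In the fits without 1 library 15 gene lists and 4 marker lists kept their call each time. Without the 4 libraries with lung transcripts camera called 13 gene lists, 12 of them among the 18, and without the 9 libraries 14, of which 13. The calls lost were those of calcium handling (adjusted p = 0.0592 and 0.0624), mitochondrially encoded transcripts (0.0591 and 0.166), glycolysis (0.102 and 0.238), the ATF4 response (0.0696 and 0.158), inflammation (0.0696 and 0.377), and without the 4 alone the extracellular matrix (0.0501). The smooth muscle list lost its call without the 9 libraries (0.134). Calls were gained, at the preset correlation, by fatty acid synthesis (0.0489) and white adipocytes (0.0167) without the 4 libraries, and by the glucocorticoid (0.00311), erythroid (0.0110) and white adipocyte lists (0.00143) without the 9. Of the 18 gene lists 14 were among 16 called with a surrogate variable, 16 among 18 with the B cell level and 12 among 16 with the sarcomere level as covariate. With the sarcomere level as covariate the glycolysis median turned to -0.033 and that of calcium handling to -0.00073 (camera adjusted p = 0.151 and 0.885). Calls were also lost there by nuclear oxidative phosphorylation (median 0.0092, camera adjusted p = 0.223), inflammation (-0.085, 0.616), mTOR components (0.033, 0.151), smooth muscle and pericytes (0.12, 0.0615) and the sarcomere list itself (0.014, 0.895), and the median of fatty acid oxidation went from 0.34 to 0.17. Calls gained there, at the preset correlation, were hypertrophy (median -0.35, camera adjusted p = 0.00108), fatty acid synthesis (0.29, 0.0107), sterol biosynthesis (turned to 0.055, 0.0411), heat shock (turned to -0.062, 0.0411), atrial (-0.61, 0.00149), endothelial (0.092, 0.00239) and white adipocyte lists (0.32, 0.0391). With the B cell level as covariate the B cell median turned to 0.069, in the list that supplied the covariate. Across all settings no named gene changed sign where it was called in either fit, and 8 genes that were not called, Mtor, Rptor, Rictor and Myh7 among them, did so in 13 values. Of the others 4512 kept their side of the threshold, 494 lost the call and 153 gained it. At this depth the test recovered 50% of simulated changes of log2 0.4.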

Other observations

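Other gene lists did not pass as sets, and single members of several did. Lists of heat shock proteins (median 0.07 over 16 genes), proteasome subunits (0.04 over 25), fatty acid synthesis (0.12 over 14) and p53 targets and cell cycle arrest (-0.13 over 16) did not pass (camera adjusted p = 0.336, 0.141, 0.458 and 0.154). The fatty acid synthesis median was 0.20 without control 19. Sterol biosynthesis had a median of -0.10 over 19 genes (camera adjusted p = 0.187, and a median of -0.0042 without control 19), in which Fdft1, squalene synthase, rose (0.39 ± 0.10, adjusted p = 0.0327 by edgeR) while 17 members had values below 0. In the antioxidant list (camera adjusted p = 0.998) Nqo1 rose (0.49 ± 0.13, 0.0389) and Ucp2 fell. The autophagy and lysosome list was split, with 12 of 24 genes above 0, a median of -0.0037, a mean of 0.0066 and a camera adjusted p of 0.722, and the cathepsin Ctsl fell (-0.29 ± 0.06, adjusted p = 0.0176 by edgeR). The glucocorticoid list had a median of -0.01 and a mean of -0.20 while the test pointed up (camera adjusted p = 0.632), with Dusp1 up and Lcn2 down. Without control 19 its median turned to 0.12. In each of these lists the counts adjusted over the list alone were the same as over all genes.

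Further cell marker lists did not pass: neutrophils and mast cells (median -0.69, camera adjusted p = 0.0944, with 2 falls that rested on control 19, and 4 when adjusted over the list alone), erythroid cells (-0.84, 0.962), endocardial and lymphatic endothelium (-0.23, 0.290, with 1 fall when adjusted over the list alone), white adipocytes (0.14, 0.274), brown adipocytes (0.30, 0.127), skeletal muscle (0.05, 0.960) and Schwann cells and neurons (-0.11, 0.755). In the last the myelin enzyme Cnp fell (-0.66 ± 0.15, adjusted p = 0.0270 by edgeR). Without control 19 the median of endocardial and lymphatic endothelium was -0.12 and that of skeletal muscle turned to -0.02. Without the 9 libraries with lung, liver or thymus transcripts the erythroid median turned to 0.64 and that of white adipocytes was 0.90 (camera adjusted p = 0.0110 and 0.00143 at the preset correlation), and the white adipocyte median was 0.48 without the 4 with lung transcripts (0.0167). Over all 20 libraries the mean erythroid level differed by 0.07 log2 units (2-sided permutation p = 0.904). Tissue taken along with the heart varied between libraries of either group, in CPM without scaling factors: brown fat Ucp1 had a median of 15.2 CPM and a highest value of 124 CPM in rapamycin 3, and the globin Hba-a1 a median of 167 and a highest value of 1328 CPM in control 17.

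The deposited counts list the mitochondrial genes ND4L, COX2, COX3, ATP6 and ATP8 at 0 in all 20 libraries. Without scaling factors COX1 had a median of 89783 CPM and CYTB of 39313 CPM in the same libraries, and ND3 one of 2.88 CPM. No level of the genes listed at 0 can be read from this table.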
